A study of Mus musculus with 7 samples.

How the data were processed

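Whole thymus RNA from 7 mice aged 8 weeks was hybridised to Illumina expression arrays, 1 array per mouse. The genotype labels gave 3 RelB-/- mice and 4 RelB+/- mice, and the sample titles called the RelB+/- mice wild type. Per the labels, biotin-labelled cRNA was prepared from total RNA. All 7 arrays lay on 1 chip, where the genotypes alternated along positions A to G.

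Probe intensity values were deposited as exported, on a linear scale and without normalization between arrays, per the file headers. GenomeStudio is named in the submitters' processing notes. Its version, the export settings and the number of beads per probe were not given in the sources used here. A detection p-value for each probe and array accompanied the deposited signals, per the file headers. The authors also deposited a table of processed values that behaves as log2 values for bright probes. Within each array its probe order equalled that of the raw signals (Spearman correlation at least 0.999998, across probes). The median of that table was 7.65 on each array, and dim probes were compressed. How the authors made it, and its exact transformation, were not given in the sources used here. No column of per-sample values was left out.

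From the raw signals, background was corrected by the normexp method of limma 3.58.1 in R 4.3.3, using the detection p-values in place of control probes and an offset of 16. Quantile normalization and a log2 transformation followed. Among 25695 probes, 23976 had 1 gene symbol in the platform annotation, 1719 had none and 0 had several. The gene identifiers of 23960 probes matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used only for names and for which genes neighbour each other. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 12465 probes. The kept probe with the highest mean over all arrays stood for each gene, giving 9569 genes, of which 725 were probes without a symbol. Among the called genes, 10 had another kept probe, and these 10 probes had the sign of the first, with fitted log2 folds from -1.84 to -0.16 in lower genes and 0.99 in the higher one, so the size of a change depends on the probe.

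The genotypes were compared with limma's linear model and moderated test (lmFit and eBayes, no intensity trend, 2-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 4 measured members. The 34 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named Relb, then up to 12 genes with the largest log2 fold in each direction among called genes whose groups did not overlap. It then named up to 4 called members per list, or the 2 members with the smallest p where none was called. Genes named outside the rule are marked as chosen after their values were seen. Clone names and probes without a symbol were counted and not named.

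A probe that passed the detection threshold on no array of 1 group has only a bound there. A gene was counted as not above background in a group only if this held for all its probes, kept or left out by the filter. The bound set the probe's mean in the brighter group against the mean, per array of the dimmer group, of the higher of the lowest detected signal and the probe's own value. Values are normalized log2 intensities. The difference is RelB-/- minus RelB+/-, SE comes from the limma fit and SD from the arrays of a group. Offsets and background shrink the fold of dim genes. The number of arrays limits the precision of every value.

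The gene test was tried on simulated data for this comparison, with 9569 genes and independent normal values at the normalized gene level. Background correction, normalization between arrays, the detection filter and the floor of dim probes were not simulated. Of the genes changed by a log2 fold of 1, 69% were called, against 98% at a log2 fold of 2, and 7 unchanged genes were called. Alternatives covered background correction, offset, normalization, the authors' processed values, the detection filter, the variance model, array weights, probe averaging, a replicate block, chip position, thresholds, the list test and each array left out in turn. After the data were seen, 3 more were added, namely leaving out 2 arrays with heart muscle transcripts, the adipocyte list mean as a covariate, and lists without the Ccl21 probes. For a list in an alternative, the value given is the relative mean, the mean log2 fold of its members minus that of all other genes. Figures were drawn with matplotlib 3.10.9.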

Results

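RelB is a subunit of the NF-kB transcription factors, acting mainly in the alternative branch of that pathway. Thymus transcriptomes of 3 RelB-/- and 4 RelB+/- mice, all 8 weeks old, were compared to find the genes that differ between the genotypes. Median raw intensity per array ranged from 103.5 to 142.3, and 11785 to 12705 probes per array (45.9% to 49.4%) were detected above background. Correlations between arrays across genes lay between 0.953 and 0.986.

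Relb itself (probe ILMN_1246841) was detected on 4 of 4 RelB+/- arrays and on 0 of 3 RelB-/- arrays. Its level was 7.09 ± 0.064 (SD, n = 4) in RelB+/- thymus and 4.46 ± 0.20 (SD, n = 3) in RelB-/- thymus. Before normalization, its raw intensity was 223, 180, 253 and 308 on RelB+/- arrays 1 to 4 and 102, 118 and 121 on RelB-/- arrays 1 to 3. The gene was at least 4.48-fold lower in RelB-/- thymus (limma adjusted p = 0.000173). The part of the transcript that the disruption removes was not given in the sources used here, so the place of the probe relative to it is unknown.

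Of 9569 genes, 64 were lower and 10 were higher in RelB-/- thymus at an adjusted p under 0.05. At a preset correlation the medullary epithelial and chemokine lists shifted lower and the granulocyte list, highest within each genotype on the array with heart muscle transcripts, shifted higher. With an estimated correlation these 3 list calls were lost (adjusted p = 0.058, adjusted p = 0.182 and adjusted p = 0.211). At an unadjusted p under 0.05 the numbers were 603 lower and 658 higher. All 74 called genes had groups that did not overlap, which largely follows from the call and adds no support to it. Of all genes, 13.6% had groups that did not overlap, against 5.71% by chance. A 2-fold difference was reached by 60 of the lower and 8 of the higher genes, and 22 of the lower genes had no probe above background on any RelB-/- array. Without RelB-/- 1 the counts were 34 lower and 6 higher, and without RelB+/- 1 they were 41 and 6. Without RelB+/- 3 they were 47 and 4. Heart muscle transcripts were present on RelB-/- 3 and RelB+/- 2, and leaving out both arrays, an alternative chosen after seeing the data, gave 26 lower and 6 higher.

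**Figure D1:**
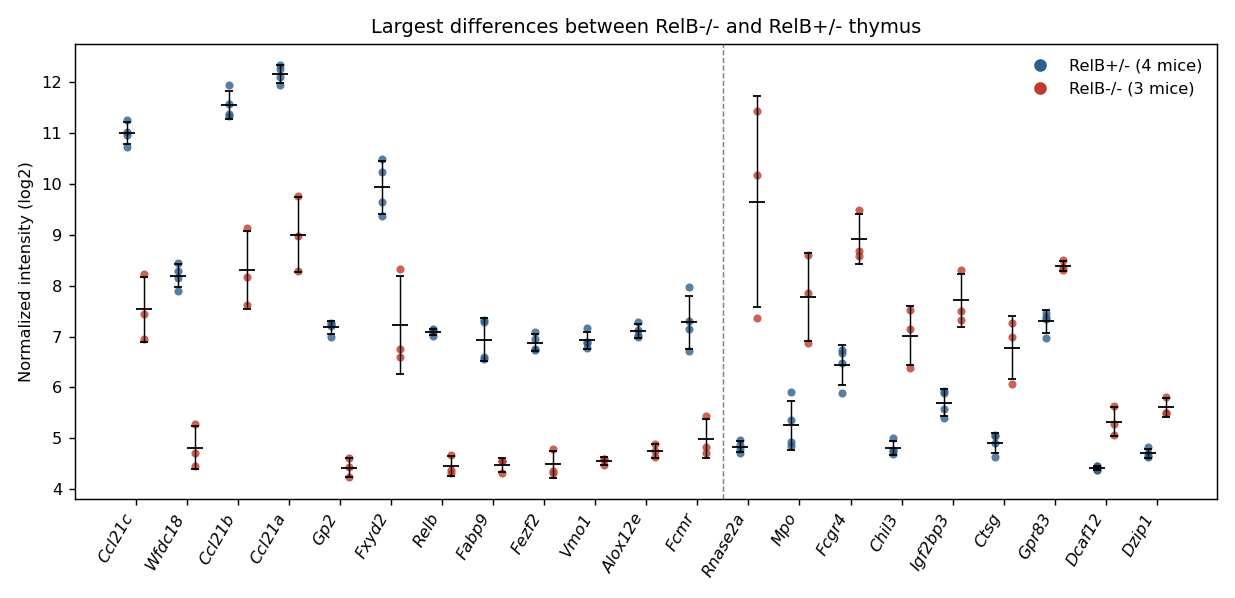
Normalized log2 intensity of the named genes with the largest differences, 12 lower (left of the dashed line) and 9 higher in RelB-/- thymus. Each point is 1 mouse, bars give mean and SD, and the groups do not overlap for any of these genes (Relb is 7.09 in RelB+/- and 4.46 in RelB-/- thymus).

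The medullary epithelial list shifted lower in RelB-/- thymus. Of 18 measured members of this list 6 were lower and 0 higher, or 10 lower when adjusted over the list alone, with a median log2 fold of -1.01 (camera adjusted p = 9.59e-13; adjusted p = 0.058 with an estimated correlation). Ccl21a, a chemokine that attracts thymocytes bearing CCR7, fell from 12.2 ± 0.18 (SD, n = 4) to 9.01 ± 0.74 (SD, n = 3), a log2 difference of -3.16 (SE 0.31, adjusted p = 0.0026). The probes of Ccl21b (-3.25, SE 0.33) and Ccl21c (-3.46, SE 0.28) fell as well, but these genes are near-identical copies and their probes may not tell them apart. Without the Ccl21 probes, left out of the lists after seeing the data, the list still had a camera adjusted p of 6.0e-08. Fezf2, a transcription factor of medullary epithelium, was detected on 4 of 4 RelB+/- and 0 of 3 RelB-/- arrays and was at least 3.87-fold lower (adjusted p = 0.00057). Aire and Krt14 complete the called members and were chosen after their values were seen. Aire, the regulator of tissue-restricted antigen expression, was at least 2.93-fold lower (adjusted p = 0.00073) by its brightest probe and at least 1.47-fold lower by another kept probe. Neither was detected on a RelB-/- array, and a dim probe of Aire that was left out by the filter was detected on 1 of 3 RelB-/- and 0 of 4 RelB+/- arrays. The keratin gene Krt14 fell by 1.68 (SE 0.26, adjusted p = 0.028), a call lost without RelB-/- 2 or any single RelB+/- array (adjusted p 0.055 to 0.091), without a detection filter (0.0503) and without the heart arrays (0.068).

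Among genes described as Aire-induced, 3 were measured, too few for a list test, and 2 were lower (3 when adjusted over the list alone). Gp2, a glycoprotein of pancreatic zymogen granules, was at least 4.75-fold lower (adjusted p = 0.000173) and was detected on 0 of 3 RelB-/- arrays. Csn2, the milk protein beta-casein, fell by 1.96 on the log2 scale (SE 0.21, adjusted p = 0.0034) and was detected on 1 of 3 RelB-/- arrays. Its call was lost with the authors' processed values (-0.44, adjusted p = 0.073) and without the heart arrays (-1.77, adjusted p = 0.0501). In the list of keratinocyte-like and tuft-like medullary epithelium 1 of 6 measured members was lower, or 2 adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.182 with an estimated correlation). That member, Krtdap, a keratinocyte differentiation gene, fell by 1.84 (SE 0.16, adjusted p = 0.0015) and was detected on 1 of 3 RelB-/- arrays. Its call was lost with the replicate block (adjusted p = 0.056). The median of this list was -0.49, or -0.31 with members not above background at their bound. Cortical epithelium had 0 of 12 members called, or 2 lower adjusted over the list alone, and a median of -0.19 (camera adjusted p = 0.064). The list was called lower without RelB+/- 2 (relative mean -0.37, adjusted p = 0.017) or RelB-/- 2 (-0.44, 0.0027). It was also called lower in 4 other alternatives, so whether it shifted stays unsettled. Its keratins Krt8 (-0.94, SE 0.27, adjusted p = 0.232) and Krt18 (-0.97, SE 0.27, adjusted p = 0.215) did not pass the test.

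The remaining genes with the largest falls were spread over several functions. Wfdc18 fell by 3.38 (SE 0.22, adjusted p = 0.00040) and was detected on 1 of 3 RelB-/- arrays. Alox12e, an epidermal lipoxygenase, fell by 2.36 (SE 0.14, adjusted p = 0.00023) and was also detected on 1 of 3. Vmo1 was at least 3.98-fold lower (adjusted p = 0.00023) by its brightest probe, while another kept probe, also detected on 0 of 3 RelB-/- arrays, gave a bound of 1.48-fold. Fabp9, a fatty acid binding protein, was at least 4.03-fold lower (adjusted p = 0.0022), a call lost with the authors' processed values (-0.60, adjusted p = 0.073). Fxyd2, a regulator of the sodium pump, fell by 2.71 (SE 0.44, adjusted p = 0.035), and by 1.84 by another probe. Its call was lost without any single array except RelB-/- 2, with log2 folds from -2.90 to -2.39 and adjusted p from 0.060 to 0.131. Fcmr, the Fc receptor for IgM, fell by 2.29 (SE 0.30, adjusted p = 0.012). Its call was lost without RelB-/- 1 (-2.15, adjusted p = 0.068) and with the authors' processed values (-0.65, adjusted p = 0.131).

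The chemokine and dendritic cell lists shifted lower at the preset correlation. Of 23 measured chemokines 6 were lower and 0 higher, or 12 lower and 1 higher adjusted over the list alone, with a median of -0.61 (camera adjusted p = 2.33e-07; adjusted p = 0.182 with an estimated correlation). Of the 23, 7 had positive log2 folds, among them Ccl8 (2.15, SE 0.54, adjusted p = 0.165), which was chosen after its value was seen. The Ccl21 probes made up 3 of the 6 called members, and the list without them had a camera adjusted p of 0.000714. Ccl5, a chemokine of T and NK cells, fell by 1.41 (SE 0.17, adjusted p = 0.0070), a call lost with the replicate block (adjusted p = 0.083). Ccl17, a ligand of CCR4, was at least 2.05-fold lower (adjusted p = 0.048) and Cxcl10, a ligand of CXCR3, fell by 1.21 (SE 0.17, adjusted p = 0.016). Conventional dendritic cell genes had 3 of 11 members lower, or 5 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 7.56e-05; adjusted p = 0.173 with an estimated correlation). They were Ccl17, Fscn1, an actin-bundling protein of mature dendritic cells (-1.83, SE 0.26, adjusted p = 0.019), and Socs2, a cytokine signalling inhibitor (-1.03, SE 0.18, adjusted p = 0.045). All 12 measured genes of MHC class II presentation had negative log2 folds, with a median of -0.57 and 1 lower gene, or 6 adjusted over the list alone (camera adjusted p = 3.05e-08; adjusted p = 0.173 with an estimated correlation). The lower gene was Ifi30, a thiol reductase of antigen processing (-0.83, SE 0.14, adjusted p = 0.044, and -0.50 by another probe). Leaving out single arrays ended the calls of Ccl17 (6 of 7 arrays, all but RelB+/- 3, adjusted p 0.059 to 0.177), Cxcl10 (RelB+/- 1, RelB-/- 1, RelB-/- 2 and RelB+/- 3, 0.057 to 0.073), Fscn1 (RelB-/- 1, RelB-/- 2, RelB+/- 3 and RelB-/- 3, 0.063 to 0.077), Socs2 (all but RelB-/- 3, 0.100 to 0.172) and Ifi30 (each of 7, 0.080 to 0.133).

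The list of invariant NKT and NK cells shifted lower, with 2 of 15 members lower, or 7 adjusted over the list alone, and a median of -0.49 (camera adjusted p = 5.83e-06; adjusted p = 0.211 with an estimated correlation). These were Ccl5 and Klre1, an NK cell receptor gene that was at least 1.88-fold lower (adjusted p = 0.0033). The call of Klre1 was lost without background correction (-0.34, adjusted p = 0.109), with the authors' processed values (-0.22, 0.159) and without the heart arrays (-1.22, 0.055). The B cell list shifted lower, with 0 of 11 members called on either scale and a median of -0.21 (camera adjusted p = 0.011; adjusted p = 0.509 with an estimated correlation). Its call was lost without RelB+/- 4 (adjusted p = 0.062). The plasma cell list had 1 of 6 members lower, or 2 adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.016; adjusted p = 0.211 with an estimated correlation). That gene, Mzb1, which serves immunoglobulin assembly, fell by 1.29 (SE 0.22, adjusted p = 0.039), a call lost without any single array except RelB+/- 2 (adjusted p 0.073 to 0.135). The type I interferon list shifted lower with 0 of 21 members called, or 4 lower adjusted over the list alone, and a median of -0.14 (camera adjusted p = 0.016; adjusted p = 0.509 with an estimated correlation). Its call was lost without RelB-/- 3 (adjusted p = 0.142), without the heart arrays (0.235) and with array weights (0.057).

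The granulocyte list shifted higher in RelB-/- thymus. All 15 measured members had positive log2 folds, 3 were higher, or 12 adjusted over the list alone, and the median was 2.13 (camera adjusted p = 2.72e-11; adjusted p = 0.211 with an estimated correlation and 0.0504 by fry). Mpo, the myeloperoxidase of neutrophil granules, was 7.78 ± 0.87 (SD, n = 3) against 5.26 ± 0.49 (SD, n = 4), a log2 fold of 2.53 (SE 0.41, adjusted p = 0.034). Dim probes of Mpo left out by the filter were each detected on 2 of 3 RelB-/- and 0 of 4 RelB+/- arrays. Their bounds were only 1.03-fold and 1.35-fold higher. Chil3, a chitinase-like protein of myeloid cells, rose by 2.22 (SE 0.25, adjusted p = 0.0059) and was detected on 1 of 4 RelB+/- arrays. Another kept probe of Chil3 rose by 0.99 (SE 0.20), and the call was lost with the authors' processed values (0.57, adjusted p = 0.091). Ctsg, the granule protease cathepsin G, rose by 1.87 (SE 0.27, adjusted p = 0.021) and was detected on 2 of 4. Relative to the RelB+/- mean, the list averaged 1.18, 1.86 and 2.60 on RelB-/- arrays 1 to 3 and -0.35, 0.91, -0.69 and 0.13 on RelB+/- arrays 1 to 4. The highest array of each genotype, RelB-/- 3 and RelB+/- 2, also held heart muscle transcripts. The call of Mpo was lost without RelB+/- 2, RelB-/- 2, RelB+/- 3, RelB-/- 3 or RelB+/- 4 (adjusted p 0.074 to 0.124). That of Ctsg was lost without RelB+/- 1, RelB+/- 2, RelB-/- 2, RelB+/- 3 or RelB-/- 3 (0.051 to 0.080). Without both heart arrays neither was called (Mpo 2.52, adjusted p = 0.155, and Ctsg 1.63, adjusted p = 0.107). Nor was either called with the authors' processed values (Mpo 0.87, adjusted p = 0.159, and Ctsg 0.46, adjusted p = 0.146).

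Outside that list, Rnase2a, of the eosinophil-associated ribonuclease family, had the largest rise, with a log2 fold of 4.82 (SE 0.78, adjusted p = 0.034). The RelB-/- arrays read 10.2, 7.37 and 11.4 against a RelB+/- mean of 4.83 ± 0.11 (SD, n = 4), where 1 of 4 arrays detected it. Its call was lost without RelB-/- 1 or any single RelB+/- array (adjusted p 0.072 to 0.141) and without both heart arrays (3.95, adjusted p = 0.094). It was also lost without background correction (2.85, adjusted p = 0.149) and with the authors' processed values (2.35, 0.206). Fcgr4, an Fc receptor of myeloid cells, rose by 2.47 (SE 0.28, adjusted p = 0.0055), and Igf2bp3, an RNA-binding protein of fetal tissues, by 2.02 (SE 0.26, adjusted p = 0.010). The call of Igf2bp3 was lost with the authors' processed values (0.73, adjusted p = 0.082). A dim probe of Igf2bp3 left out by the filter, detected on 2 of 3 RelB-/- and 0 of 4 RelB+/- arrays, gave a bound of 1.23-fold higher. Gpr83, a receptor gene in the regulatory T cell list, rose by 1.10 (SE 0.16, adjusted p = 0.019), and its call was lost without RelB-/- 1, RelB+/- 2, RelB-/- 2, RelB+/- 3 or RelB-/- 3 (0.056 to 0.095). Dcaf12 and Dzip1 were not above background on any RelB+/- array and were at least 1.36-fold (adjusted p = 0.047) and 1.65-fold higher (adjusted p = 0.030). When single arrays were left out, Dcaf12 kept its call only without RelB-/- 3 and Dzip1 only without RelB+/- 4, with adjusted p otherwise 0.093 to 0.153 and 0.075 to 0.093. The eosinophil and mast cell list had 0 of 6 members called, or 1 higher adjusted over the list alone, and its median (-0.050) and mean (0.38) differed in sign. Its measured members other than Prg2 (Cpa3, Mcpt4, Tpsb2, Cma1 and Fcer1a) are mast cell or basophil genes. The list result therefore says little about eosinophils. Prg2, the major basic protein of eosinophil granules, had a log2 fold of 3.42 (SE 0.71, adjusted p = 0.102) and was higher on 3 of 3 RelB-/- arrays. It was called without RelB+/- 2 (3.97, adjusted p = 0.039), without the heart arrays (3.30, 0.022) and with the adipocyte list mean as a covariate (4.15, 0.011), the last 2 chosen after seeing the data.

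Thymocyte lists differed little. The double-positive thymocyte list shifted higher by a median of 0.17, with 0 of 19 members called on either scale (camera adjusted p = 0.027; adjusted p = 0.620 with an estimated correlation). Without RelB-/- 1, RelB+/- 2, RelB-/- 2 or RelB+/- 4 its call was lost (0.068 to 0.191). Among its members, Bcl6 had a log2 fold of 0.57 (SE 0.21, adjusted p = 0.332) and Rag2 of 0.56 (SE 0.23, adjusted p = 0.363). Mature single-positive thymocytes (median 0.083, adjusted p = 0.762), early progenitors (0.27, 0.751), gamma-delta and innate lymphoid cells (0.18, 0.446) and cell cycle genes (-0.028, 0.446) were not called by camera, and none of their members passed the test. Regulatory T cell genes had 1 of 19 members higher, or 3 higher and 1 lower adjusted over the list alone, with a median of -0.035 and a mean of 0.075 (camera adjusted p = 0.762). Of 23 NF-kB pathway genes the lower one was Relb, on either scale, and the median was -0.049 (camera adjusted p = 0.446).

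**Figure D2:**
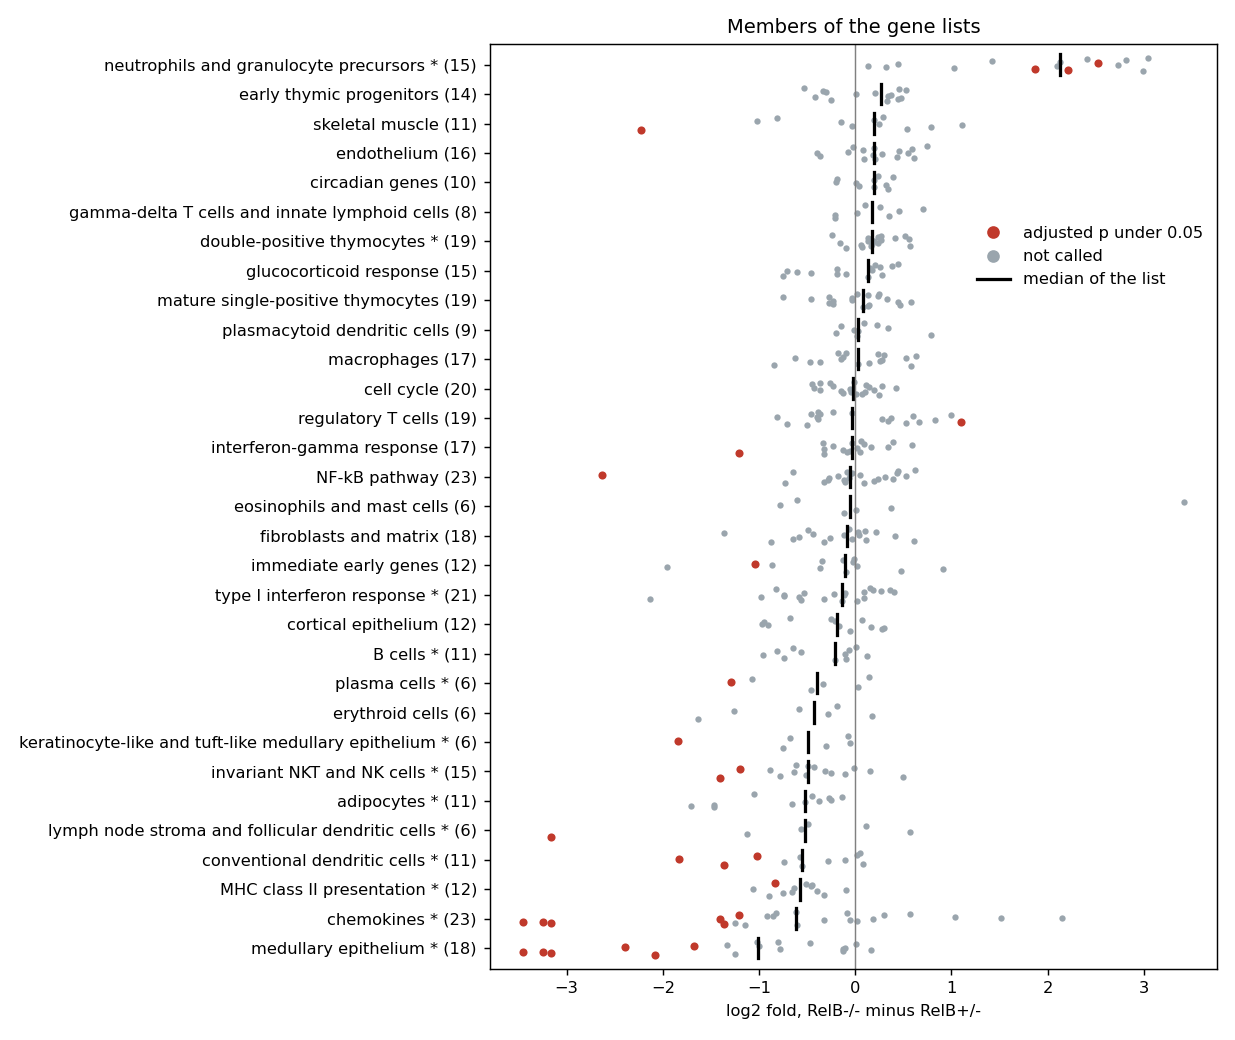
Log2 fold (RelB-/- minus RelB+/-) of each measured member of the 31 tested lists, 1 point per gene, with the number of members in brackets. Vertical bars are list medians, red points have an adjusted p under 0.05 and an asterisk marks a camera adjusted p under 0.05 at the preset correlation. The medullary epithelium median is -1.01 and the granulocyte median 2.13.

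In all, 13 of 31 tested lists were called at the preset correlation, 11 lower and 2 higher, 0 with an estimated correlation and 6 by fry, which does not compare a list with other genes. The adipocyte list shifted lower, with 0 of 11 members called on either scale and a median of -0.52 (camera adjusted p = 0.023; adjusted p = 0.642 with an estimated correlation). Its mean per array was -1.61, -1.52 and 0.86 on RelB-/- arrays 1 to 3, and its call was lost without RelB-/- 1, RelB+/- 2, RelB-/- 2 or RelB+/- 4 (0.079 to 0.371). Leaving out each array in turn, its relative mean ranged from -1.56 to -0.34, with a lowest adjusted p of 1.9e-09. Its member Adipoq was called lower without RelB-/- 3 (-2.42, adjusted p = 0.042). The list of lymph node stroma and follicular dendritic cells had 1 of 6 members lower on either scale, Ccl21a, with a median of -0.53, or -0.39 with members not above background at their bound (camera adjusted p = 0.027; adjusted p = 0.555 with an estimated correlation). Without the Ccl21 probes its adjusted p was 0.387, and without RelB-/- 1 or RelB+/- 4 it was 0.146 to 0.209. Actn3, the alpha-actinin of fast muscle fibres, was at least 4.14-fold lower (adjusted p = 0.00057) by its brightest probe and at least 1.32-fold lower by another kept probe (unadjusted p = 0.057). Neither was detected on a RelB-/- array, and a dim probe of Actn3 left out by the filter was detected on 1 of 3 RelB-/- and 0 of 4 RelB+/- arrays. Actn3 was the 1 lower member of 11 in the skeletal muscle list, or 3 lower and 1 higher adjusted over the list alone, whose median (0.20) and mean (-0.097) differed in sign (camera adjusted p = 0.280). Without RelB-/- 3 that list was called lower (relative mean -0.53, adjusted p = 0.033).

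Some genes stood apart on 1 or 2 arrays. Xist, the RNA of the inactive X chromosome, was at 9.15 on RelB-/- 2, where the Y-linked Eif2s3y was at 4.34 and not detected. On the other arrays Eif2s3y lay between 6.60 and 7.63 and Xist was not detected. By these transcripts RelB-/- 2 was a female and the other mice were males, although the labels gave no sex. Only the RelB-/- group thus mixed the sexes, and an effect of sex was not tested. Without RelB-/- 2, 47 genes were lower and 8 higher. The atrial muscle genes Nppa and Sln were high on RelB-/- 3 (12.6 and 11.9) and RelB+/- 2 (9.98 and 10.7), and at most 5.02 elsewhere.

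**Figure D3:**
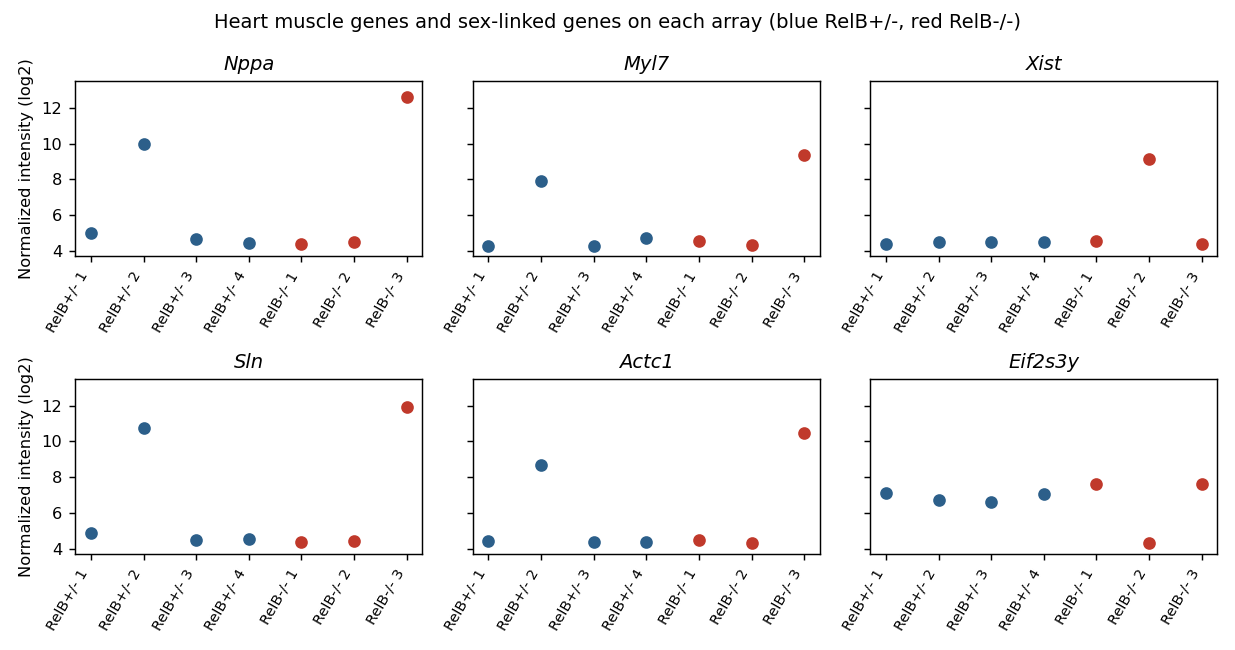
Normalized log2 intensity of heart muscle genes (Nppa, Sln, Myl7, Actc1) and sex-linked genes (Xist, Eif2s3y), 1 point per mouse. The heart genes are high on RelB-/- 3 and RelB+/- 2 only, and Xist (9.15) on RelB-/- 2 only.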

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

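The tests on neighbouring genes, blood and heart tissue were chosen after the results were seen. The predictions for other splits and fat were written before, but the fit with the adipocyte list mean was added after the data were seen.

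Genes lower in RelB-/- thymus numbered 64, and 1 of the 35 splits of the 7 arrays, the real one, gave as many. The highest of the others was 0. That argues against chance but cannot exclude it, since 1 of 35 is the smallest share that these arrays allow. The other splits also mix the genotypes, so their counts are not those of arrays without a genotype difference. With the adipocyte list mean as a covariate their median log2 fold was -1.66 against -1.68 without it and 49 of 64 kept their call, which argues against fat as the whole cause. Of 80 measured neighbours of Relb, 40 on each side, 0 were lower, and 53 of the 61 lower named genes other than Relb were not placed on its chromosome, which argues against DNA of another strain around the gene as the whole cause. As a part of it that cannot be told apart: 13.1% of the lower genes lay on that chromosome against 7.95% of the others, too few to decide (Fisher's exact test, 2-sided, p = 0.149), and 15% of the neighbours against 13.1% of other genes had an unadjusted p under 0.05. A lower number of medullary cells and a lower level per cell remain open, as neither was tested.

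Genes higher in RelB-/- thymus numbered 10, and 2 of the 35 splits gave as many, so chance cannot be excluded for this number. The highest other value, 11, came from RelB+/- arrays 1, 2 and 3 against the rest, and all 11 of these were histone genes. For the granulocyte genes, more blood or bone marrow would bring erythroid transcripts, but the erythroid list had a median log2 fold of -0.43 (range -1.63 to 0.18). Relative to the RelB+/- mean it averaged -0.48, -0.87 and -0.53 on RelB-/- arrays 1 to 3. On RelB+/- arrays 1 to 4 it averaged -0.76, -0.27, -0.034 and 1.06, so the size of the fall rests largely on RelB+/- 4. The 6 measured members show no rise, which argues against more blood or bone marrow of the same make-up as the whole cause. Given the spread among RelB+/- arrays, they cannot exclude a smaller contribution. Over the 5 arrays without heart transcripts the granulocyte list was higher in RelB-/- thymus by 1.82, beyond the SD of 0.41 among their RelB+/- arrays. The lowest RelB-/- value was 1.18 and the highest RelB+/- value 0.13, which argues against heart tissue carried along as the whole cause. As a part of the rise it cannot be told apart from genotype: the lower of RelB-/- 1 and 2 exceeded the highest RelB+/- array, which held heart transcripts, by 0.27, less than the SD of 0.69 among RelB+/- arrays. More granulocytes in the blood or the thymus of RelB-/- mice stay open and untested.

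Sln was at 11.9 on RelB-/- 3 and 10.7 on RelB+/- 2 but failed the detection filter, and its signal was one of 14 probes left out by the filter yet over 3 log2 units above their own median over the arrays. Of 19 heart genes listed after this was seen, 14 were highest on these arrays. Of the 19 listed genes, 9 had no probe among those 14 probes left out by the filter, and 3 of the 9 were detected on no array. On this pair 5 of the 9 were highest (Mybpc3, Myl3, Myl4, Nppa and Tnni3), against at most 1 on any other of the 21 pairs. Heart tissue carried along would give such a count. It is not independent of the pattern, since the genes were listed after it was seen and Nppa and Myl4 show it strongly. Mybpc3 was detected on 1 array only. Ectopic expression by medullary epithelium would be lower where Aire and Fezf2 are not detected, yet the RelB-/- array was higher by a median of 1.79 (0.94 to 2.62) over the 12 genes that stood over 1 log2 unit above the other 5 arrays on both, which argues against it. No biological explanation was tested beyond that.

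Of 103 sets of 4 RelB+/- values, 4 had an array far from the others, where chance gives about 5%. Junb was at 9.87 on RelB+/- 4 against 9.57 to 9.60. Kdr was at 4.48 on RelB+/- 2 against 5.01 to 5.06. Prg2 was at 8.81 on RelB+/- 2 against 6.46 to 6.75. The interferon-gamma list mean was -0.076 on RelB+/- 4 against 0.017 to 0.035. Among probes left out by the filter, Xist was at 9.15 on RelB-/- 2 against at most 4.57 elsewhere, and Actb at 9.05 on RelB+/- 4 against at most 5.20.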

How the results depend on the processing

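Leaving out the arrays with heart transcripts, the adipocyte covariate and the lists without Ccl21 probes were chosen after seeing the data. All 74 called genes kept their sign in every setting where they were tested, and Relb kept its call in each of them, but the stricter filter did not test it. The number of lower and of higher genes, 64 and 10 in the main setting, was 40 and 5 without background correction, 23 and 2 with the authors' processed values, 14 and 3 for probes detected on all 7 arrays, 31 and 2 at an adjusted p under 0.01, and 26 and 6 without the 2 arrays with heart transcripts. The stricter filter tested only 26 of the 74 called genes, and leaving out arrays reduces the samples; the other causes were not tested. Higher genes numbered 6 without a detection filter and 28 with the adipocyte covariate, when 54 were lower. Leaving out each array in turn gave 34 to 65 lower and 4 to 8 higher genes. With the replicate block the numbers were 23 lower and 1 higher. Whether the numbers in the titles pair the samples stays unsettled. Residuals of same-numbered arrays correlated at 0.32, -0.18 and -0.20, and 1 of 3 RelB-/- arrays correlated best with its own number. These are too few arrays to decide. Of 33 called genes named by the rule, 11 kept their call in every alternative of processing and model, 15 lost it when some single array was left out, and 7 only in another alternative (Ccl5, Krtdap, Chil3, Csn2, Fabp9, Igf2bp3 and Klre1). Without the heart arrays, Ccl17, Csn2, Ctsg, Cxcl10, Dcaf12, Dzip1, Fcmr, Fscn1, Fxyd2, Gpr83, Ifi30, Junb, Klre1, Krt14, Mpo, Mzb1, Rnase2a and Socs2 lost their call. With the authors' processed values, Ccl17, Chil3, Csn2, Ctsg, Cxcl10, Dcaf12, Dzip1, Fabp9 and Fcmr lost their call. So did Fscn1, Fxyd2, Igf2bp3, Klre1, Mpo, Mzb1, Rnase2a and Socs2. Lists called were 13 in the main setting, 0 with an estimated correlation, 6 by fry and 9 to 14 in all others.

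Some lists outside the main calls were called elsewhere. Cortical epithelium was called lower at offset 50 (adjusted p = 0.047), with the stricter filter (0.039), with the mean of the probes (0.0072), with the adipocyte covariate (0.0060) and without RelB+/- 2 (0.017) or RelB-/- 2 (0.0027). Endothelium was called higher with the adipocyte covariate (0.60, adjusted p = 1.1e-05) and without RelB-/- 1 (0.020). Fibroblasts were called lower without the heart arrays (-0.72, 0.0011) and without RelB-/- 3 (0.0030), skeletal muscle without RelB-/- 3 (0.033) and immediate early genes without RelB+/- 3 (0.026).

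Only lists and genes that were not called changed sign. The relative mean of macrophages (main 0.00893) was -0.059 without background correction, -0.037 at offset 50 and -0.072 with the authors' values. It was -0.107 with the stricter filter, -0.064 without the heart arrays and -0.029 to 0.071 leaving out arrays in turn. The other lists are given likewise. Skeletal muscle (main -0.095) was 0.039, 0.057 and 0.040 without background correction, with the authors' values and with the stricter filter, 0.30 with the adipocyte covariate, and -0.53 to 0.14 in turn. Cell cycle (main -0.044) was 0.0082 with median centring, 0.035 without the heart arrays and -0.13 to 0.023 in turn. The NF-kB pathway, where the stricter filter drops Relb, was 0.011 there. Mature single-positive thymocytes (main 0.029) were at -0.0079 with the replicate block, -0.015 with the adipocyte covariate and -0.051 to 0.081 in turn. Fibroblasts (main -0.20) were at 0.13 with the replicate block, 0.21 with the adipocyte covariate and -0.63 to 0.13 in turn. Endothelium (main 0.22) was -0.12 without the heart arrays and -0.21 to 0.46 in turn. Eif2s3y (main -0.34) was 0.018 with the authors' values, 0.040 with the adipocyte covariate and -0.89 to 0.76 in turn, and Cox6a2 (main 0.79) was -0.34 to 1.62 in turn. With arrays left out in turn, Eif2s3y was positive only without RelB-/- 2, where it was at 4.34 and Xist at 9.15. Cox6a2 was negative only without RelB-/- 3. It was at 11.3 there, at 10.1 on RelB+/- 2, the other array with heart transcripts, and at 7.01 to 8.42 elsewhere. Beyond these arrays the causes were not tested. Signal over background limits dim genes, since the probes of 25 lower genes have only a bound in RelB-/- thymus; with these at their bound the median log2 fold of the lower genes was -1.51 in place of -1.68.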

Other observations

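Several lists that bear on the state of the tissue were not called. Immediate early genes had 1 of 12 members lower, or 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.204). Their median was -0.11, or -0.059 with members not above background at their bound. But the list was called lower without RelB+/- 3 (relative mean -0.40, adjusted p = 0.026). Junb, a subunit of AP-1, fell by 1.04 (SE 0.16, adjusted p = 0.028), a call lost when any single array was left out (adjusted p 0.059 to 0.080). The interferon-gamma list had 1 of 17 members lower on either scale, Cxcl10, with a median of -0.035 (adjusted p = 0.446). Glucocorticoid response genes had 0 of 15 called, or 1 lower adjusted over the list alone, and their median (0.13) and mean (-0.065) differed in sign (adjusted p = 0.759). Circadian genes had a median of 0.19 with 0 of 10 called (adjusted p = 0.446).

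Macrophages had a median of 0.029 with 0 of 17 members called, or 1 lower adjusted over the list alone (camera adjusted p = 0.913). Plasmacytoid dendritic cells had a median of 0.032 with 0 of 9 called (adjusted p = 0.762), endothelium 0.20 with 0 of 16 (0.388), fibroblasts and matrix -0.090 with 0 of 18 (0.446) and erythroid cells -0.43 with 0 of 6 (0.204). Single arrays decided 2 of these: endothelium was called higher without RelB-/- 1 (relative mean 0.46, adjusted p = 0.020), and fibroblasts lower without RelB-/- 3 (-0.63, 0.0030). Too few genes were measured to test the thyroid and parathyroid list (0 of 3 called, median -1.36, or -0.98 with members not above background at their bound) and the sex-linked list (0 of 2 called, median -0.31). Pth, the parathyroid hormone gene, ranged from 4.28 to 8.21 across arrays with a log2 fold of -1.60 (SE 0.74, adjusted p = 0.403).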
